A study of Mus musculus with 45 samples.

How the data were processed

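Each sample was the total RNA of a subcutaneous CT26 tumour, sequenced as 150-nucleotide paired-end reads on an MGISEQ-2000RS after library preparation with an MGIEasy kit, per the labels' protocols. Treatment by intraperitoneal injection, 2 times a week, began at day 8, when tumours measured 90 to 100 mm3. Antibodies were given at 10 mg/kg, except for a group given HLX53 at 5 mg/kg in T2106. The submitters' processing notes name FastQC, Trimmomatic, STAR and Bowtie and the builds hg19, mm10 and GRCh37, without versions or roles. The program that made the expression values is not given in the sources used here.

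The deposited tables hold log2 values for 47729 mouse genes, 1 column per tumour, in a table per experiment. Raised from the log2 scale the values of a library summed to between 678636 and 911201, and 53.5% to 57.4% of the genes lay below −9, so the values were read as log2 FPKM. The FPKM unit fits the file headers and the sums, and counts were not used here. The read depth behind a value is unknown, so no interval for counting error is given. The tables were normalised separately by the authors, so the experiments were never fitted together, and T2106 and T2215 are the experiment codes of the labels. All 45 columns were assigned to their groups from the sample labels.

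Values were returned to FPKM and tested as log2(FPKM + 0.5). A fold change on this scale understates the change of genes near or below 0.5 FPKM. Genes with an FPKM of 0.5 or more in at least 3 libraries were tested, 15070 in T2106 and 14914 in T2215. Each experiment was fitted with all its groups in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), so all groups shared an estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, and 0.05 was the threshold. The p-values measure spread between tumours. There were 22 comparisons, 8 in T2106 and 14 in T2215. In T2215 the antibody classes and the antibodies within a class were averaged with equal weight over the levels of the other class, and the interaction was the mean of the 4 combinations, minus the means of the single agents of each class, plus vehicle.

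A set of 26 gene lists with 400 members was written before the data were examined, as were the tests, the comparisons and the rule for named genes. The lists covered T cell identity, CD8 T cells and cytotoxic effectors, checkpoint receptors, regulatory T cells, naive and memory T cells, natural killer cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells, interferon gamma response, type I interferon response, MHC class I, MHC class II, cell cycle, hypoxia and glycolysis, fibroblasts and matrix, endothelium, epithelium and carcinoma, skeletal muscle, skin keratinocytes, adipocytes, erythrocytes, immediate early and stress genes, and mitochondrial transcripts. The list members H2-L (MHC class I) and Ahsp (erythrocytes) matched no gene symbol and were not analysed here. Lists with at least 4 tested members were tested with limma's fry, adjusted over the lists. Its p-value tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Camera with an estimated correlation between genes, which does compare a list with other genes, was run beside it. Counts described as adjusted over the list alone used Benjamini-Hochberg values within that list. A list score is the mean of log2(FPKM + 0.5) over the tested members in a tumour, and the score of a group is given with its SD.

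The genes named were, per comparison, up to 6 with the largest rise and up to 6 with the largest fall among those past the threshold. Gene models named Gm with a number or ending in Rik, and antigen receptor segments, were left out. Other gene models without a functional name, such as AC125149.1 and AI506816, were kept. To these were added up to 4 members with the smallest p of each list that passed, a fixed panel of 18 immune genes in every comparison, and Pdcd1 and Tigit in every group. Genes chosen by this rule whose values are left out of the text are not reported here. Gene models 2610021A01Rik, Gm43199 and Gm43802 were named after their values were seen. Coordinates are those of the GENCODE M21 annotation on GRCm38, in which 175 of 176 named genes were found by their identifiers. Genes that overlap another gene, and pseudogenes that resemble their parent genes, can share reads, and the strand of counting is not given in the sources used here.

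Correlations across tumours used Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, Benjamini-Hochberg adjusted over 8 relations. Fold changes of treatments given in both experiments were correlated over the 14646 genes tested in both, with a jackknife over libraries for the error. The difference of list effects between experiments was tested by exact permutation of the treated and vehicle labels within each experiment, 400 relabellings, two-sided. Comparisons that share vehicle libraries were not correlated or overlapped with each other.

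The procedure was tested on simulated data with 200 changed genes outside the lists, 50 at each fold, beside a lowered cell cycle list whose genes also count among the calls. For serplulimab with HLX53 against vehicle in T2106 (15070 genes) limma recovered 26% of the genes changed 1.5-fold, 50% at 2-fold, 84% at 4-fold and 96% at 8-fold, with 2 unchanged genes among 134 calls. For HLX53 against tiragolumab in T2215 (14914 genes) it recovered 72%, 88%, 96% and 100%, with 9 unchanged genes among 210 calls. A simulated fall of the cell cycle list was called in both. The noise was drawn independently for each gene, without the correlation between genes that the real tumours have. The shares recovered, the false calls and the list call therefore do not carry over to the real tables.

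The alternatives chosen before the data were examined were pseudocounts of 0.1 and 1, no filter on low values, centring each library on its median log2 ratio, the replicate number as a block, a fit of only the groups compared, leaving out each library in turn, and camera. Added after the data were seen were a fit without the tumours whose skeletal muscle score exceeded 1.5 and, in T2106, a fit with the adipocyte score as a covariate. The muscle score was added as a covariate for HLX53 against tiragolumab alone. The name of the series mentions LAG3, and the sample labels hold no group given an antibody against it.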

Results

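Bulk RNA was sequenced from 45 subcutaneous tumours of CT26, a colon carcinoma line from BALB/c mice, grown in BALB/c mice with knocked-in human PD-1 and human TIGIT genes. PD-1 and TIGIT are inhibitory receptors of T cells and natural killer cells. The mice received vehicle or antibodies against them: serplulimab or pembrolizumab against PD-1, and HLX53 or tiragolumab against TIGIT. The tumours came from 2 experiments with separate tables. T2106 held 18 tumours in 6 groups of 3: vehicle, serplulimab, HLX53, pembrolizumab with tiragolumab, and serplulimab with HLX53 at 5 mg/kg or at 10 mg/kg. T2215 held 27 tumours in 9 groups of 3, crossing no PD-1 antibody, serplulimab or pembrolizumab with no TIGIT antibody, HLX53 or tiragolumab, each at 10 mg/kg. Each library listed between 12918 and 14448 genes at an FPKM of 0.5 or more, and the read depth behind the values is unknown. Replicate tumours of a group correlated at 0.83 to 0.99 in T2106 and at 0.89 to 0.99 in T2215. Component 1 of a principal component analysis held 69.5% of the variance in T2106 and 47.2% in T2215.

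The mouse counterparts of the knocked-in genes were read first. Pdcd1, which encodes PD-1 (ENSMUSG00000026285; GRCm38 chromosome 1, 94038305 to 94052553, minus strand), had a mean of 1.38 ± 0.685 FPKM (SD, n = 3) in the vehicle group of T2106. Its mean was 0.947 ± 0.495 with serplulimab, 1.89 ± 0.97 with HLX53, 0.366 ± 0.284 with pembrolizumab and tiragolumab, 3.09 ± 3.72 with serplulimab and HLX53 at 5 mg/kg, and 2.66 ± 0.90 at 10 mg/kg. In T2215 Pdcd1 had 2.00 ± 1.16 FPKM with vehicle, 1.70 ± 2.62 with serplulimab, 0.420 ± 0.12 with pembrolizumab, 0.936 ± 0.506 with HLX53 and 0.801 ± 0.913 with tiragolumab. The combinations had 1.70 ± 0.949 (serplulimab and HLX53), 0.419 ± 0.315 (serplulimab and tiragolumab), 1.04 ± 0.616 (pembrolizumab and HLX53) and 0.287 ± 0.18 (pembrolizumab and tiragolumab). Tigit (ENSMUSG00000071552; chromosome 16, 43648867 to 43664146, minus strand) was higher, at 16.2 ± 2.33 FPKM with vehicle in T2106, 13.8 ± 6.19 with serplulimab, 16.5 ± 0.619 with HLX53, 15.6 ± 1.65 with pembrolizumab and tiragolumab, and 11.6 ± 6.72 and 6.19 ± 4.93 with serplulimab and HLX53 at 5 and 10 mg/kg. In T2215 Tigit had 11.8 ± 4.3 with vehicle, 10.8 ± 5.75 with serplulimab, 14.3 ± 2.77 with pembrolizumab, 11.7 ± 4.09 with HLX53 and 13.5 ± 2.6 with tiragolumab. The combinations had 7.55 ± 4.14 (serplulimab and HLX53), 12.7 ± 1.67 (serplulimab and tiragolumab), 9.78 ± 3.68 (pembrolizumab and HLX53) and 15.9 ± 1.67 (pembrolizumab and tiragolumab). The tables list mouse genes, so these are reads assigned to the mouse gene models.

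Mouse Pdcd1 followed the T cell genes across tumours, and mouse Tigit ran opposite to them. Over the 27 tumours of T2215, Pdcd1 correlated with the mean of the T cell list at r = 0.917 (rho = 0.948), and over the 18 of T2106 at r = 0.916 (rho = 0.917). Each of these had a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 4e-05 over 8 relations. Without the 2 tumours farthest from the median, r was 0.908 and 0.863. Tigit against the T cell list gave r = −0.608 in T2215 (permutation p = 0.00045, adjusted p = 6e-04, rho = −0.692 with p = 8e-05, and r = −0.527 without the 2 farthest). Against the cell cycle list, genes of dividing cells, Tigit gave r = 0.721 (permutation p = 0.00015, adjusted p = 0.00024, rho = 0.459 with p = 0.0167, and r = 0.472 without the 2 farthest). In T2106 3 libraries stood apart, and the values were −0.835 and 0.896. For deviations from the group means in T2215, r of Tigit was −0.454 with the T cell list and 0.689 with the cell cycle list.

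**Figure D1:**
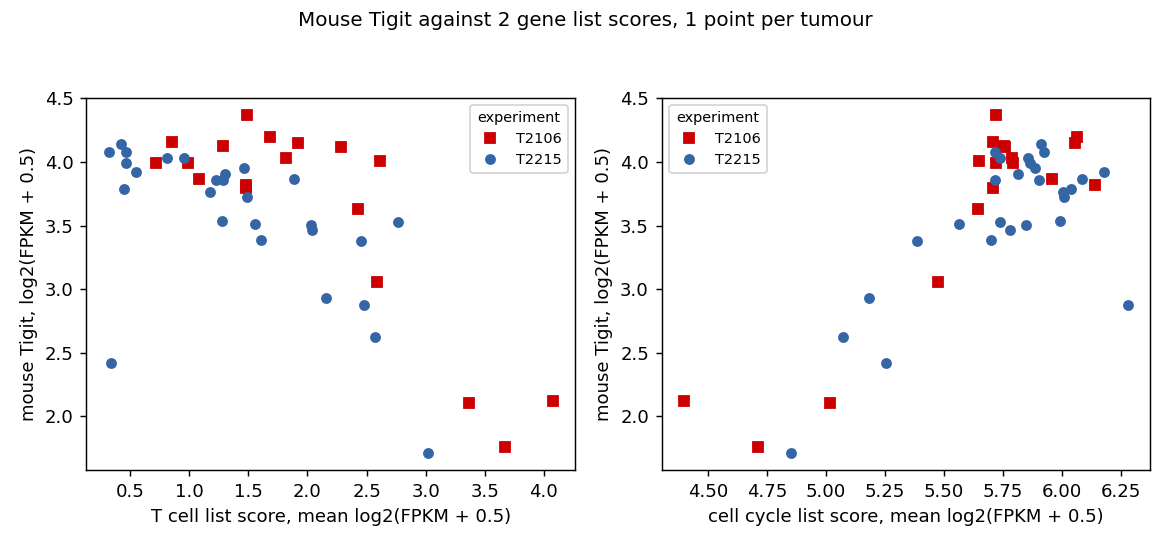
Mouse Tigit in each tumour, as log2(FPKM + 0.5), against the mean log2(FPKM + 0.5) of the T cell list and of the cell cycle list, with squares for T2106 and circles for T2215. In T2215 r was −0.608 with the T cell list and 0.721 with the cell cycle list.

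Serplulimab with HLX53 at 10 mg/kg against vehicle asked what the PD-1 and TIGIT pair did to the tumours of T2106. Genes of myeloid cells, lymphocytes, connective tissue and fat were higher, and genes of cell division were lower. By fry 18 of 26 lists moved, while camera with an estimated correlation called 0, with 2 at an unadjusted p under 0.05. Saa3, an acute phase protein, rose by 7.01 ± 1.13 on the log2 scale (SE, n = 3 in each group), from 6.47 ± 3.87 to 811 ± 280 FPKM (SD). Ctsk, a collagen-degrading protease, rose from 2.66 ± 1.85 to 459 ± 289 FPKM (7.07 ± 1.49). The other large rises were Igkc, the kappa light chain constant region (6.74 ± 1.45), Sfrp2, a secreted Wnt modulator (6.49 ± 1.34), Retnla, a marker of alternatively activated macrophages (6.38 ± 0.96), and Cpxm1 (6.19 ± 1.28). The 6 largest falls were of Rpl35a-ps3 (−7.08 ± 2.41), AC125149.1 (−5.76 ± 1.88), Rpl14-ps1 (−4.29 ± 1.47), Cdh26 (−3.41 ± 0.94), Glod5 (−3.06 ± 0.97) and Dkk2, a Wnt pathway regulator (−2.96 ± 0.60). Rpl35a-ps3 and Rpl14-ps1 are ribosomal protein pseudogenes that can share reads with their parent genes, and Rpl35a-ps3 ranged from 0.747 to 1030 FPKM among the vehicle tumours. In all 6633 of 15070 genes changed by limma, 3532 higher and 3101 lower. With the adipocyte score as a covariate, a choice made after the data were seen, 3 genes passed, 2 of them shared, and 2 lists. Of the named genes that had passed, Cd4, Cd74, H2-Aa, H2-DMb1, Lrrc32, Klf2 and Pecam1 changed sign in that fit. Of the variance of the score 75.1% lay between groups, so part of a treatment effect could be removed with it. The smallest adjusted p was 3.14e-05, and 8443 genes had an unadjusted p under 0.05. The count was 505 without serplulimab and HLX53 replicate 1, 965 without its replicate 3, and 3199, 3781 and 4308 without vehicle replicates 1, 2 and 3.

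The myeloid lists rose. Of 15 neutrophil genes 13 rose (13 adjusted over the list alone), with a median of 2.39 and an adjusted p of 0.0067. They included the calprotectin subunits S100a8 (4.96 ± 0.82) and S100a9 (5.00 ± 0.84), Retnlg (4.09 ± 0.63) and Lcn2 (2.07). Of 16 macrophage and monocyte genes 12 rose (13 adjusted over the list alone; median 1.56, adjusted p = 0.0272), among them the scavenger receptor Cd163 (4.26), Adgre1, which encodes F4/80 (2.43), Cd68 (1.75) and Cd14 (1.0). Of 15 dendritic cell genes 11 rose (13 adjusted over the list alone; median 1.48, adjusted p = 0.0272), with Clec10a at 4.77, the chemokine Ccl22 at 2.32 and the transcription factor Irf8 at 1.62. Mast cell genes rose on balance, 5 of 9 with 1 fall (6 and 1 adjusted over the list alone; median 1.22, adjusted p = 0.0289), with Hdc at 1.82, Kit at 1.22, Tpsb2 at 1.32 and Gata2 at −1.29. Of 10 MHC class II genes 5 rose (10 adjusted over the list alone; median 1.75, adjusted p = 0.0322), among them H2-Eb1 (3.06 ± 0.95), H2-Aa (3.12 ± 1.04), H2-DMb1 (1.92) and the invariant chain Cd74 (2.13). With an estimated correlation between genes (camera) each of these lists had an adjusted p of 0.443. The adipocyte score stood at 5.87 to 6.17 in the tumours of this group and at 0.687 to 6.13 in the other T2106 tumours.

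Lymphocyte lists rose in the same tumours. B and plasma cell genes rose, 9 of 10 (10 adjusted over the list alone; median 1.92, adjusted p = 0.0214), with Jchain at 4.81, Mzb1 at 2.87 and Cd79a at 2.17. Of 18 CD8 and cytotoxic genes 7 rose (7 adjusted over the list alone; median 1.18, adjusted p = 0.0304), led by Ifng, the interferon gamma gene (1.66 ± 0.36), Gzmb, granzyme B (1.27 ± 0.38), Gzmk (2.04 ± 0.63) and Cst7 (1.14). Prf1, the gene of perforin, rose by 1.44 ± 0.49 and Cd4 by 2.49 ± 0.73, while Cd3e stood at 0.96 ± 0.71 and Cd8a at 1.15 ± 0.77 without passing (adjusted p = 0.265 and 0.218). Checkpoint receptors rose on balance, 6 of 12 with 1 fall (6 and 1 adjusted over the list alone; median 0.93, adjusted p = 0.0427): Havcr2, the TIM-3 gene, at 1.77 ± 0.47, Entpd1 at 1.67 and Cd96 at 1.33, against Tigit at −1.56 ± 0.50. Of 9 regulatory T cell genes 5 rose (7 adjusted over the list alone; median 1.0, adjusted p = 0.0272), Il2ra by 1.60, Lrrc32 by 2.67, Ctla4 by 1.51 and Tnfrsf18 by 1.31. Foxp3 at 0.99 did not pass (adjusted p = 0.0507). Of 9 naive and memory T cell genes 5 rose (7 with 1 fall adjusted over the list alone; median 1.19, adjusted p = 0.0427), Ccr7 by 2.27, Il7r by 2.04, S1pr1 by 1.69 and Klf2 by 0.64. Of 6 natural killer cell genes 3 rose (4 adjusted over the list alone; median 0.70, adjusted p = 0.0272), Klrg1 by 1.63, Klra3 by 0.74 and Klrb1c by 0.61, beside Ncr1 at 0.88 (adjusted p = 0.0659). With an estimated correlation the adjusted p was 0.453 for the checkpoint and the naive and memory lists and 0.443 for the others. These lists were read in tumours whose adipocyte score was 6.04 ± 0.158, against 2.15 ± 1.53 with vehicle.

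The T cell identity list did not pass (median 1.39, 9 of 21 genes higher both over all genes and adjusted over the list alone, adjusted p = 0.0502), nor did interferon gamma response (median 0.53, 7 of 24 higher and 4 adjusted over the list alone, adjusted p = 0.0594) or MHC class I (median 0.39, 3 of 16 higher and 1 adjusted over the list alone, adjusted p = 0.0665). With libraries centred on their medians these lists passed, at 0.0398, 0.0406 and 0.0389. With the adipocyte score as a covariate, a choice made after the data were seen, the median of the T cell list was −0.286. Cd274, which encodes PD-L1, rose by 1.90 ± 0.47. Cxcl9 at 0.33 (adjusted p = 0.624), Cxcl10 at 0.31 (0.376), B2m at 0.03 (0.908), H2-K1 at −0.01 (0.968), Lag3 at 0.98 (0.144) and Pdcd1 at 0.78 ± 0.65 (0.326) did not pass. Type I interferon genes had a median of 0.06 with none of 19 past the test (adjusted p = 0.785), and hypoxia and glycolysis genes a median of 0.06 (2 of 18 higher and 1 lower, with 2 and 0 adjusted over the list alone, adjusted p = 0.785).

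Connective tissue, vessel, fat, epithelial and skin genes rose in the same tumours. Fibroblast and matrix genes had a median of 2.70, with 15 of 19 higher (16 adjusted over the list alone; adjusted p = 0.0272), among them the matrix genes Postn (5.87 ± 1.29), Col5a2 (5.12) and Lum (4.58) and the fibroblast protease Fap (3.56). Endothelial genes had a median of 1.48 with 11 of 16 higher (15 adjusted over the list alone; adjusted p = 0.0304), Vwf by 2.59, Tek by 2.05, Pecam1 by 1.59 and Cldn5 by 1.56. All 11 adipocyte genes rose (11 adjusted over the list alone; median 4.28, adjusted p = 0.0138), among them the lipid droplet genes Plin1 (4.28 ± 0.97) and Plin4 (3.09), the leptin gene Lep (1.95) and Pnpla2 (1.07). Of 15 epithelial genes 10 rose and 1 fell (11 and 2 adjusted over the list alone; median 2.31, adjusted p = 0.00032), with Epcam at 3.39 ± 0.61, Cldn7 at 2.33 and Krt18 at 1.64. Of 11 skin keratinocyte genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.18, adjusted p = 5.19e-05), with the basal keratins Krt5 (2.96 ± 0.45, from 0.132 to 4.32 ± 0.0944 FPKM) and Krt14 (2.57 ± 0.33), Krt17 (1.93) and Krt15 (1.14). The skin score was 1.44 to 1.61 in these tumours and at most 1.13 in the other T2106 tumours. With an estimated correlation the adjusted p of each of these lists was 0.443.

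Cell cycle genes fell, 21 of 23 over all genes and 23 adjusted over the list alone (median −0.98, adjusted p = 0.0272, and adjusted p = 0.443 with an estimated correlation). Among them were the cyclin Ccna2 (−1.39 ± 0.35), Tyms (−1.07), Bub1b (−1.05) and the proliferation marker Mki67 (−0.89 ± 0.22). The cell cycle score was 6.09 ± 0.05 with vehicle and 5.12 ± 0.48 with the pair (SD, n = 3). Immediate early and stress genes rose on balance, 7 of 19 with 2 falls (7 and 2 adjusted over the list alone; median 0.41, adjusted p = 0.0272, and adjusted p = 0.443 with an estimated correlation): Fos by 2.30, Btg2 by 1.89 and Dusp1 by 0.95, with Jun at −0.48. Mitochondrial transcripts (median −0.30, 1 of 13 higher and 3 lower, 0 adjusted over the list alone, adjusted p = 0.117), skeletal muscle (0.65, 1 of 5 higher and 0 adjusted over the list alone, 0.556) and erythrocyte genes (0.08, none of 5 past the test, 0.69) did not pass. Of the 18 lists moved by fry 17 rose and 1 fell, 20 had an unadjusted p under 0.05, and camera called 0. The number of lists was 4 without vehicle replicate 1, 6 without vehicle replicate 2, and 4 without replicate 1 or replicate 3 of the pair. The skin, epithelial and neutrophil lists passed in all 6 of these refits.

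**Figure D2:**
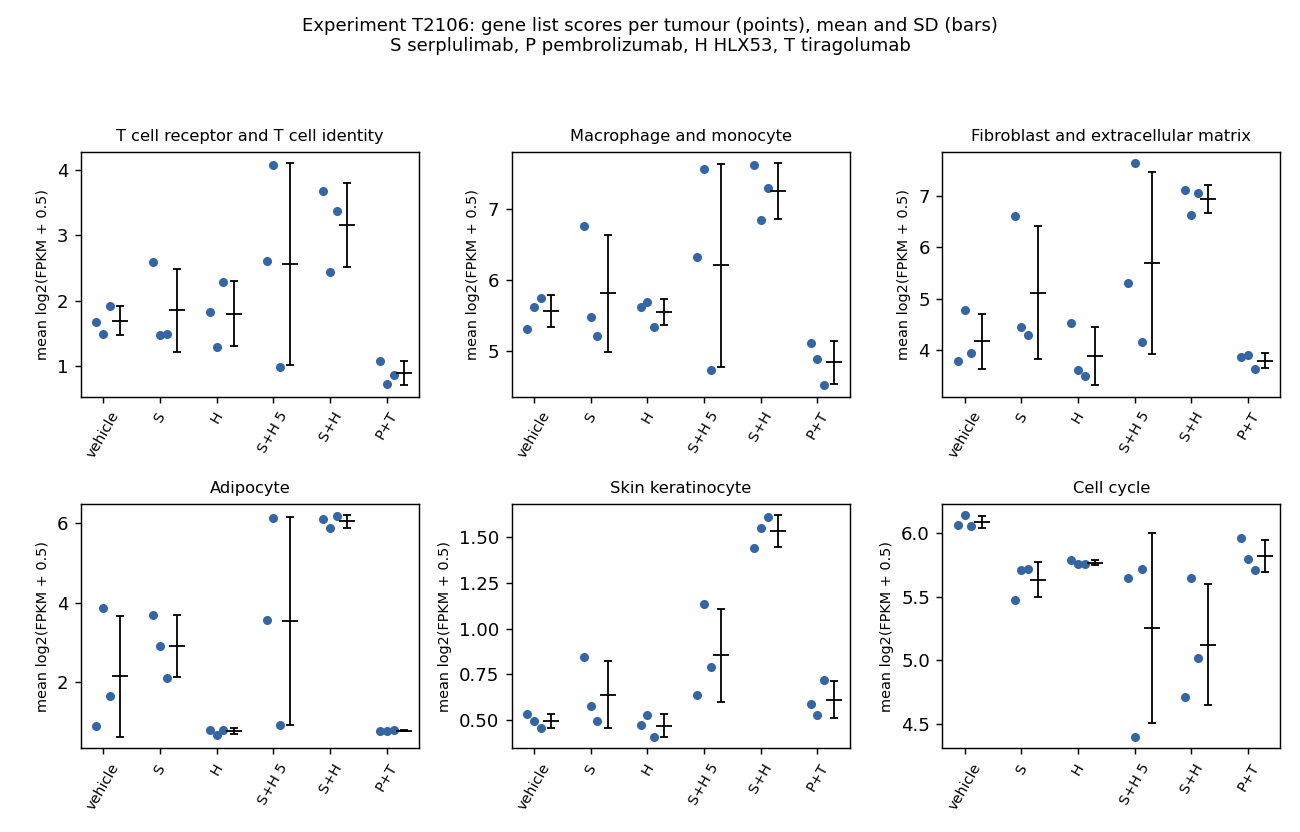
Mean log2(FPKM + 0.5) of 6 gene lists in the 18 tumours of T2106, with a point per tumour and bars for the mean and SD of each group. The adipocyte score was 5.87 to 6.17 and the skin score 1.44 to 1.61 with serplulimab and HLX53 at 10 mg/kg, and the cell cycle score 5.12 ± 0.48 against 6.09 ± 0.05 with vehicle.

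At the lower dose of HLX53, 5 mg/kg with serplulimab, the neutrophil genes S100a8, S100a9 and Retnlg were among those higher than with vehicle in T2106. Saa3 rose by 5.37 ± 1.13, S100a9 by 4.58 ± 0.84, S100a8 by 4.30 ± 0.82, Retnlg by 3.51 ± 0.63, Nos2, the inducible nitric oxide synthase, by 3.51 ± 0.57 and Prl2c2 by 3.44 ± 0.50 (SE, n = 3 in each group). The largest falls were of Inmt, a methyltransferase (−1.94 ± 0.23), Dio2, which activates thyroid hormone (−1.90), Hjurp (−1.29), Trim16 (−1.23), AI506816 (−1.21) and Ston1 (−1.21). Of 15 neutrophil genes 4 rose (11 adjusted over the list alone; median 1.95, adjusted p = 0.0219, and adjusted p = 0.425 with an estimated correlation), Lcn2 by 2.42. Immediate early and stress genes rose, 2 of 19 over all genes and 12 adjusted over the list alone (median 0.69, adjusted p = 0.000154), led by Jund (0.82) and the heat shock gene Hspa1b (1.96), beside Hspa1a at 2.25 (adjusted p = 0.0527) and Dusp1 at 0.98 (0.0632). Mitochondrial transcripts fell on balance (median −0.64, adjusted p = 0.0219, and adjusted p = 0.425 with an estimated correlation), with none of 13 past the test by limma over all genes and 8 lower adjusted over the list alone. Ifng at 1.60 (adjusted p = 0.0505), Cd274 at 1.99 (0.0534) and Mki67 at −0.93 (0.0534) did not pass. Neither did interferon gamma response (median 0.76, 2 of 24 higher and 10 adjusted over the list alone, adjusted p = 0.0776) or cell cycle genes (median −0.83, 0 of 23 over all genes and 21 lower adjusted over the list alone, adjusted p = 0.0857).

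In this comparison 154 of 15070 genes changed by limma, 53 higher and 101 lower, with a smallest adjusted p of 0.000995 and 4331 at an unadjusted p under 0.05. With libraries centred on their medians 81 changed, 62 higher and 19 lower. The tumours differed widely: the adipocyte score was 3.58, 6.13 and 0.926 in replicates 1, 2 and 3 of the treated group. The skeletal muscle score of replicate 2 was 2.97. Without replicate 1, 2 or 3 of the treated group 896, 17 or 6082 genes changed. Without vehicle replicate 1, 2 or 3 it was 21, 15 or 12. By fry 3 lists moved and 7 had an unadjusted p under 0.05. Camera with an estimated correlation called 1, the immediate early list (adjusted p = 0.0131). Without vehicle replicate 2 or treated replicate 2 there was 1 list, and without treated replicate 3 there were 20. When only the 6 libraries compared were fitted, limma called 0 genes and fry 0 lists.

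Stress genes had higher values with the single agents than with vehicle in T2106. The vehicle group, shared by these comparisons, had the lowest stress score of the 6 groups (3.96 ± 0.23, SD) and the highest mitochondrial score (11.1 ± 0.32). In T2215 the mean stress effect was 0.19 with serplulimab and 0.33 with HLX53, and the mitochondrial effect of serplulimab was 0.05. Neither agent moved a list by fry there. With serplulimab alone immediate early and stress genes rose on balance (median 0.45, adjusted p = 0.00281, and adjusted p = 0.00751 with an estimated correlation), with the heat shock genes Hspa1b at 1.79 ± 0.32 and Hspa1a at 1.91, Ier3 at 1.25 and Hsph1 at 0.83. None of its 19 genes passed over all genes by limma, and 6 did adjusted over the list alone. Mitochondrial transcripts fell on balance (median −0.84, adjusted p = 0.0258, and adjusted p = 0.268 with an estimated correlation), with mt-Nd5 at −0.88 ± 0.25, mt-Nd1 at −0.84, mt-Atp8 at −1.22 and mt-Nd4 at −0.92. Again 0 of 13 passed by limma over all genes, and 6 were lower adjusted over the list alone. With median centring the list did not pass (adjusted p = 0.0845). Gzmb stood at 1.09 (adjusted p = 0.497), Cd274 at 1.24 (0.516), Ifng at 0.83 (0.547) and Cd8a at −0.34 (0.883). Limma called 0 genes, with a smallest adjusted p of 0.292 and 1280 at an unadjusted p under 0.05. Of the lists 2 moved by fry with 4 at an unadjusted p under 0.05, camera called 1, and 1 moved without replicate 1, 2 or 3 of serplulimab.

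HLX53 alone lowered 1 gene in T2106, Inmt (chromosome 6, 55170626 to 55175043, minus strand), by −1.75 ± 0.23 (adjusted p = 0.0237 by limma), from 2.65 ± 0.637 to 0.459 ± 0.31 FPKM (SD, n = 3). Inmt did not pass without vehicle replicate 2 or 3 or without HLX53 replicate 1 or 3, each of which left 0 genes, and 582 genes had an unadjusted p under 0.05. Immediate early and stress genes rose on balance, all 19 with positive values (median 0.38, adjusted p = 0.00469, and adjusted p = 0.0011 with an estimated correlation), with Hspa1b at 1.33, Hspa1a at 1.22, Junb at 0.45 and Jund at 0.30. None of these passed over all genes by limma, and 1 did adjusted over the list alone. Interferon gamma response genes were positive in 24 of 24 (median 0.82), with 16 higher adjusted over the list alone and 0 over all genes, and the list did not pass (adjusted p = 0.124). In T2215 the mean effect of HLX53 alone on this list was −0.44, against 0.89 in T2106, so the direction was not shared. Gzmb stood at 1.41 ± 0.38 (adjusted p = 0.951), Prf1 at 1.70 ± 0.49, Ifng at 1.15 and Cd274 at 1.43 (adjusted p = 1 each). By fry 1 list moved and 2 had an unadjusted p under 0.05, and camera called 1. Leaving out a library gave 1 or 2 lists.

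Pembrolizumab with tiragolumab against vehicle in T2106 left the T cell genes Cd3e and Cd8a at −1.81 ± 0.71 and −1.86 ± 0.77 (adjusted p = 0.923 and 0.937; SE, n = 3 in each group), while Gzmb stood at 1.16 (0.858), Prf1 at 1.40 (0.894) and Cd274 at 1.24 (0.92). The T cell list had a median of −0.73 (adjusted p = 0.712), interferon gamma response 0.61 (0.399), hypoxia and glycolysis 0.82 (0.319) and MHC class II −0.45 (0.819). Limma called 0 genes, with a smallest adjusted p of 0.474 and 774 at an unadjusted p under 0.05. By fry 0 of 26 lists moved, with a smallest adjusted p of 0.113 and 3 at an unadjusted p under 0.05. Camera with an estimated correlation called 1, immediate early and stress (median 0.21, adjusted p = 0.0284). Without vehicle replicate 1 there were 2 lists.

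Adding HLX53 at 10 mg/kg to serplulimab asked what the TIGIT antibody brought beside the PD-1 antibody in T2106. Epithelial and skin genes were higher. Reg1, a secreted lectin of the regenerating family, rose by 3.15 ± 0.26 (adjusted p = 8.62e-05; SE, n = 3 in each group), from 0.146 to 5.39 ± 1.99 FPKM, Reg3g, an antibacterial lectin, by 3.35 ± 0.44, Fxyd3 by 3.51 ± 0.77, Wfdc2 by 3.39, Cd209f by 3.24 and Adrb3, an adrenergic receptor of fat cells, by 3.10. The largest falls were of Dio2 (−1.97 ± 0.41), Sgcd (−1.39), Hspa1b (−1.38), Rundc3b (−1.16), Camk2b (−1.16) and Lancl3 (−1.15). Of 11 skin genes 6 rose (6 with 1 fall adjusted over the list alone; median 1.13, adjusted p = 0.000116), with Krt5 at 2.82 ± 0.45, Krt14 at 2.50 ± 0.33, Krt17 at 1.88 and Krt15 at 1.14. Of 15 epithelial genes 6 rose (10 with 2 falls adjusted over the list alone; median 2.03, adjusted p = 0.000992), with Epcam at 3.08, Cldn7 at 2.15 and Krt18 at 1.22. Both lists had an adjusted p of 0.439 with an estimated correlation. The adipocyte score was 6.04 ± 0.158 against 2.91 ± 0.782 with serplulimab alone. The adipocyte list had a median of 3.53 (1 of 11 higher, 11 adjusted over the list alone, adjusted p = 0.055). Cd3e at 1.46 (adjusted p = 0.15), Cd8a at 1.49 (0.167), Cd4 at 2.06 (0.0844) and Tigit at −1.24 (0.105) did not pass. Neither did the T cell list (median 1.30, adjusted p = 0.126), the B and plasma cell list (1.80, 10 of 10 adjusted over the list alone, 0.0996) or the endothelial list (1.41, 15 of 16 adjusted over the list alone, 0.0996). In all 240 genes changed by limma, 212 higher and 28 lower, with 5408 at an unadjusted p under 0.05. The count was 3479, 11 and 1 without serplulimab replicates 1, 2 and 3, and 24, 809 and 8 without replicates 1, 2 and 3 of the pair. Without replicate 2 of the lower dose, a muscle-rich tumour outside this comparison that entered the shared estimate of the spread, it was 5778, and 11 lists moved. By fry 2 lists moved, 10 had an unadjusted p under 0.05, 11 moved without serplulimab replicate 1, and camera called 0, with 2 at an unadjusted p under 0.05.

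The doses of HLX53 beside serplulimab, 10 against 5 mg/kg, differed in 21 genes, 4 of them in the skin list and 1 in the epithelial list. Reg1 rose by 3.22 ± 0.26 (adjusted p = 6.57e-05; SE, n = 3 in each group), Reg3g by 2.95 ± 0.44, Nnat by 2.69 ± 0.39, Krt5 by 2.47 ± 0.45, Krt14 by 2.23 ± 0.33 and Urah by 1.82 ± 0.28 at the higher dose. Cebpb, a transcription factor of myeloid and fat cells, was the 1 gene that fell (−0.77 ± 0.13, adjusted p = 0.0425). Of 11 skin genes 4 rose (6 with 1 fall adjusted over the list alone; median 0.73), with Krt17 at 1.45 and Krt15 at 0.98. Of 15 epithelial genes Krt18 rose by 1.29 (10 higher adjusted over the list alone; median 1.64), beside Epcam at 2.60 (adjusted p = 0.137). Both lists had an adjusted p of 0.00129, and adjusted p = 0.227 and 0.113 with an estimated correlation. Immediate early and stress genes fell on balance (median −0.27, adjusted p = 0.0112, and adjusted p = 0.0278 with an estimated correlation), with 0 of 19 past limma's test over all genes, 5 lower adjusted over the list alone, Hspa1b at −1.55 (adjusted p = 0.0953) and Jun at −0.51 (0.172). Adipocyte genes (median 2.63, 10 of 11 adjusted over the list alone, adjusted p = 0.201), the T cell list (0.55, 0.56), Cd8a (0.58, adjusted p = 0.72) and Ifng (0.06, adjusted p = 0.942) did not pass. By limma 20 of the 21 genes were higher and 1 lower, and 1653 had an unadjusted p under 0.05. By fry 3 lists moved with 4 at an unadjusted p under 0.05. Leaving out replicate 1, 2 or 3 at the lower dose gave 1, 5867 or 1 genes. Leaving out replicate 1, 2 or 3 at the higher dose gave 4, 10 or 2, and 14 lists moved without replicate 2 at the lower dose. With only these 6 libraries fitted, limma called 0 genes and fry 0 lists.

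The pairs of antibodies were also set against each other. In T2106 serplulimab with HLX53 stood above pembrolizumab with tiragolumab in fat, matrix, myeloid and T cell genes. By fry 16 of 26 lists moved, while camera with an estimated correlation called 0, with 0 at an unadjusted p under 0.05. Cfd, the adipokine adipsin, was higher by 9.34 ± 1.63, Car3, a carbonic anhydrase abundant in fat and muscle, by 9.15 ± 1.54, Cpxm1 by 7.36, Sfrp2 by 7.31, Ctsk by 7.25 ± 1.49 and Mup9 by 7.22 (SE, n = 3 in each group). Rpl14-ps1 (−4.66), Cdh26 (−3.31), Dkk2 (−3.20), Glod5 (−2.97), Slc14a1 (−2.80) and Krt20 (−2.66) were lower. Cd3e was higher by 2.77 ± 0.71, Cd8a by 3.01 ± 0.77, Cd4 by 3.38 ± 0.73, Foxp3 by 1.5, Lag3 by 2.01, Pdcd1 by 1.87 ± 0.65 and Ifng by 1.17, and Tigit was lower (−1.50 ± 0.50). Gzmb at 0.11 (adjusted p = 0.82), Prf1 at 0.04, Havcr2 at 0.96 (0.104), Cxcl9 at 1.01 (0.143), Cd274 at 0.66 (0.254) and Mki67 at −0.56 (0.0544) did not pass. In all 6414 genes differed by limma, 3888 higher and 2526 lower, with 8241 at an unadjusted p under 0.05. The adipocyte score as a covariate ended all of these calls by limma and those of the lists by fry. Named genes changed sign, Cd3e, Cd4, Foxp3, Pdcd1 and Tigit among them. The score was 6.04 ± 0.158 and 0.791 ± 0.013 in these groups, and its spread lay mainly within others (SD 2.60 at the lower dose, 1.53 with vehicle). The covariate therefore cannot tell fat from treatment in this comparison. The count was 1632 and 2357 without replicates 1 and 3 of serplulimab and HLX53, and 4175, 3075 and 3066 without replicates 1, 2 and 3 of pembrolizumab and tiragolumab.

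Of the 26 lists 16 were higher in that comparison, and the count adjusted over the list alone is given where it differed from the count over all genes. The T cell list had 20 of 21 genes higher (21 adjusted over the list alone; median 2.07, adjusted p = 0.0119). CD8 and cytotoxic genes had 12 of 18 (14 adjusted over the list alone; median 1.38, adjusted p = 0.0198), checkpoint receptors 7 of 12 with 1 lower (median 1.08, adjusted p = 0.0335), regulatory T cell genes 6 of 9 (7 adjusted over the list alone; median 1.28, adjusted p = 0.0129). Naive and memory genes had 7 of 9 (median 1.63, adjusted p = 0.0129), among them Klf2, S1pr1, Ccr7 and Tcf7 at 0.92, 1.97, 2.45 and 1.63. Macrophage genes had 12 of 16 higher (15 adjusted over the list alone; median 2.21, adjusted p = 0.00966), with Cd163 at 5.79 and the complement gene C1qa at 2.18. Dendritic cell genes had 14 of 15 (median 1.85, adjusted p = 0.0111), with Clec10a at 5.25, and neutrophil genes 10 of 15 (11 adjusted over the list alone; median 1.86, adjusted p = 0.016). B and plasma cell genes had 10 of 10 higher (median 2.44, adjusted p = 0.00966), with Igkc at 6.57. MHC class II genes had 9 of 10 (10 adjusted over the list alone; median 2.26, adjusted p = 0.0129), with H2-Eb1 at 3.49, and mast cell genes 5 of 9 with 1 lower (6 and 1 adjusted over the list alone; median 1.20, adjusted p = 0.0335). The fibroblast list had 16 of 19 higher (17 with 1 lower adjusted over the list alone; median 3.0, adjusted p = 0.0121), with Postn at 7.03, and endothelial genes 15 of 16 (median 2.00, adjusted p = 0.0111). Adipocyte genes were all higher (11 of 11; median 5.30, adjusted p = 0.00277), with Plin1 at 5.30. The skin (8 higher, 2 lower; 1.16, adjusted p = 7.02e-05, with Krt14 at 2.66) and epithelial lists (10 higher, 2 lower, with 10 and 3 adjusted over the list alone; 2.02, adjusted p = 0.00137) were higher as well. The adipocyte score was 6.04 ± 0.158 against 0.791 ± 0.013 with pembrolizumab and tiragolumab. With an estimated correlation the adjusted p lay between 0.485 and 0.504 for these 16 lists, and camera called 0. By fry 17 had an unadjusted p under 0.05, and 9 lists moved without replicate 1 of serplulimab and HLX53. Interferon gamma response did not pass, with a median of −0.03, a mean of 0.15 and a test direction upward (2 of 24 higher, 0 adjusted over the list alone, adjusted p = 0.869). Cell cycle (median −0.70, 8 of 23 lower and 0 adjusted over the list alone, adjusted p = 0.0688), hypoxia (−0.98, 7 of 18 lower, with 10 lower and 2 higher adjusted over the list alone, 0.101) and natural killer genes (0.52, 2 of 6 higher and 3 adjusted over the list alone, 0.13) did not pass either.

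In T2215 the antibody classes were compared across the crossed groups. PD-1 antibody against none, 18 tumours against 9, left the T cell gene Cd8a at −0.45 ± 0.47 (adjusted p = 0.733), Prf1 at −0.95 (0.673) and Mki67 at −0.21 (0.674). The adipocyte list had a median of 0.99, skeletal muscle 1.03 (0.02 without the 3 muscle-rich tumours, all given a PD-1 antibody), fibroblast and matrix 0.50 and cell cycle −0.21. By fry 0 of 26 lists passed, with a smallest adjusted p of 0.76 and 0 unadjusted, and camera called 0, with 1 unadjusted. Limma called 0 genes, with a smallest adjusted p of 0.0524 and 1085 at an unadjusted p under 0.05. It called 1 gene without replicate 1 or 2 of serplulimab and tiragolumab or replicate 2 of pembrolizumab and HLX53. Serplulimab against pembrolizumab had Cd8a at 0.50 ± 0.55 (adjusted p = 0.66) and Tigit at −0.43 (0.506). Limma called 0 genes (smallest adjusted p = 0.12, 1418 unadjusted), and fry and camera 0 lists (0 unadjusted by each; smallest adjusted p = 0.625 by fry). The count of genes was 5 without serplulimab replicate 2, and 1 without replicate 3 of serplulimab and HLX53, replicate 1 of serplulimab and tiragolumab or replicate 2 of pembrolizumab and HLX53. The interaction, what the combinations added beyond the single agents, had Cd8a at 1.66 ± 1.0, Cd4 at 1.41 ± 0.60 and Foxp3 at 0.74 ± 0.31 (adjusted p = 1 each). Its list medians were 1.47 for MHC class II, 1.07 for T cells and 0.83 for dendritic cells (adjusted p = 0.546). It gave 0 genes by limma (170 unadjusted) and 0 lists by fry (0 unadjusted) or camera (1 unadjusted).

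TIGIT antibody against none gave 2 genes higher on average in T2215, carried by 3 of the 6 groups given one, and the immune lists did not pass. The genes were 2610021A01Rik (ENSMUSG00000091474; chromosome 7, 41599230 to 41628533, plus strand), a protein-coding gene model, at 0.69 ± 0.11, and Gm43199 (ENSMUSG00000105551; chromosome 5, 55584494 to 55584800, plus strand), a processed pseudogene that can share reads with its parent gene, at 0.71 ± 0.11 (SE, 18 tumours against 9; adjusted p = 0.0279 each by limma). Against 6.14 to 7.63 FPKM with vehicle, 2610021A01Rik stood at 5.84 to 8.48 with HLX53, 6.98 to 9.08 with tiragolumab and 4.49 to 7.57 with serplulimab and HLX53, and Gm43199 was at most 1.71e-05 outside the 3 groups given serplulimab with tiragolumab, pembrolizumab with HLX53 or pembrolizumab with tiragolumab. Both lie outside the rule for named genes and were named after their values were seen. Havcr2 stood at 0.72 ± 0.26 (adjusted p = 0.747), 987 genes had an unadjusted p under 0.05, and 0 lists passed by fry (smallest adjusted p = 0.859; 0 unadjusted) or camera (0 unadjusted). The count moved with single libraries. It was 6 without serplulimab replicate 2, 1 without HLX53 replicate 2 or replicate 1 of serplulimab and tiragolumab, and 0 without any 1 library of vehicle, pembrolizumab, tiragolumab or pembrolizumab with tiragolumab. It was also 0 without replicate 1 or 3 of serplulimab, of HLX53 or of serplulimab with HLX53, and without replicate 3 of serplulimab with tiragolumab.

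HLX53 against tiragolumab, 9 tumours against 9 in T2215, compared the TIGIT antibodies over the same PD-1 arms. T cell, interferon and antigen presentation genes had higher values with HLX53, and none passed over all genes. MHC class II genes had a median of 1.46 (10 of 10 higher adjusted over the list alone, list adjusted p = 0.0687), interferon gamma response 1.09 with 24 of 24 positive (0.0858), CD8 and cytotoxic genes 1.05 (0.0858) and T cell genes 0.90 (21 of 21 higher adjusted over the list alone, 0.0687). Regulatory T cell genes had 0.62 (6 of 8 adjusted over the list alone), checkpoint receptors 0.75 (5 higher and 1 lower adjusted over the list alone), MHC class I 0.55, neutrophil genes 1.13 (5 adjusted over the list alone, 0.0687) and cell cycle genes −0.37 (18 of 23 lower adjusted over the list alone, 0.0809). Among single genes Havcr2 stood at 0.98 ± 0.29, Cd3e at 1.22 ± 0.44 and Cd274 at 1.42 ± 0.49 (adjusted p = 0.155 each), Cd8a at 1.43 ± 0.55, Gzmb at 1.28 ± 0.62 (0.188), Cxcl9 at 1.28 (0.177), Pdcd1 at 0.80 (0.176), Ifng at 0.82 (0.256) and Tigit at −0.62 ± 0.25 (0.158). The adipocyte list had a median of 0.93 (0.342). Limma called 0 genes, with a smallest adjusted p of 0.138 and 3964 at an unadjusted p under 0.05. Fry called 0 lists with 12 unadjusted, and camera 0 with 0 unadjusted, where the adjusted p of the MHC class II and T cell lists with an estimated correlation was 0.333.

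Skeletal muscle genes marked 3 of these tumours, with scores of 9.24 in serplulimab replicate 1, 3.70 in pembrolizumab and tiragolumab replicate 3 and 2.02 in serplulimab and tiragolumab replicate 2. Without them, a choice made after the data were seen, 15 lists passed by fry between HLX53 and tiragolumab, 14 up and 1 down. Within this comparison it took 2 tumours from the tiragolumab arm and 0 from the HLX53 arm, each the highest of its group in the interferon gamma score (6.22 against 5.55 and 3.77 beside serplulimab, 5.02 against 3.28 and 2.63 beside pembrolizumab), which widens the difference by itself. In that fit MHC class II had a median of 1.83 and interferon gamma response 1.48 (adjusted p = 0.021 each), T cell 1.14 and checkpoint 0.92 (0.0214 each), CD8 and cytotoxic 1.36 (0.0216), and cell cycle −0.39 (0.0482). Lists of other tissue moved with them: epithelial 0.82 (adjusted p = 0.0308) and skin 0.52 (0.0482) passed, and adipocyte, at 1.48, did not (0.152). Leaving out 1 library also moved the count of lists, to 11 without HLX53 replicate 3 or tiragolumab replicate 2, 9 without replicate 3 of serplulimab and HLX53 or of pembrolizumab and tiragolumab, 5 without replicate 2 of serplulimab and tiragolumab, and 3 without replicate 2 of pembrolizumab and HLX53. The count of genes went to 22 without replicate 2 of pembrolizumab and HLX53, 7 without replicate 3 of serplulimab and HLX53, and 1 without HLX53 replicate 3 or replicate 2 of serplulimab and tiragolumab.

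**Figure D3:**
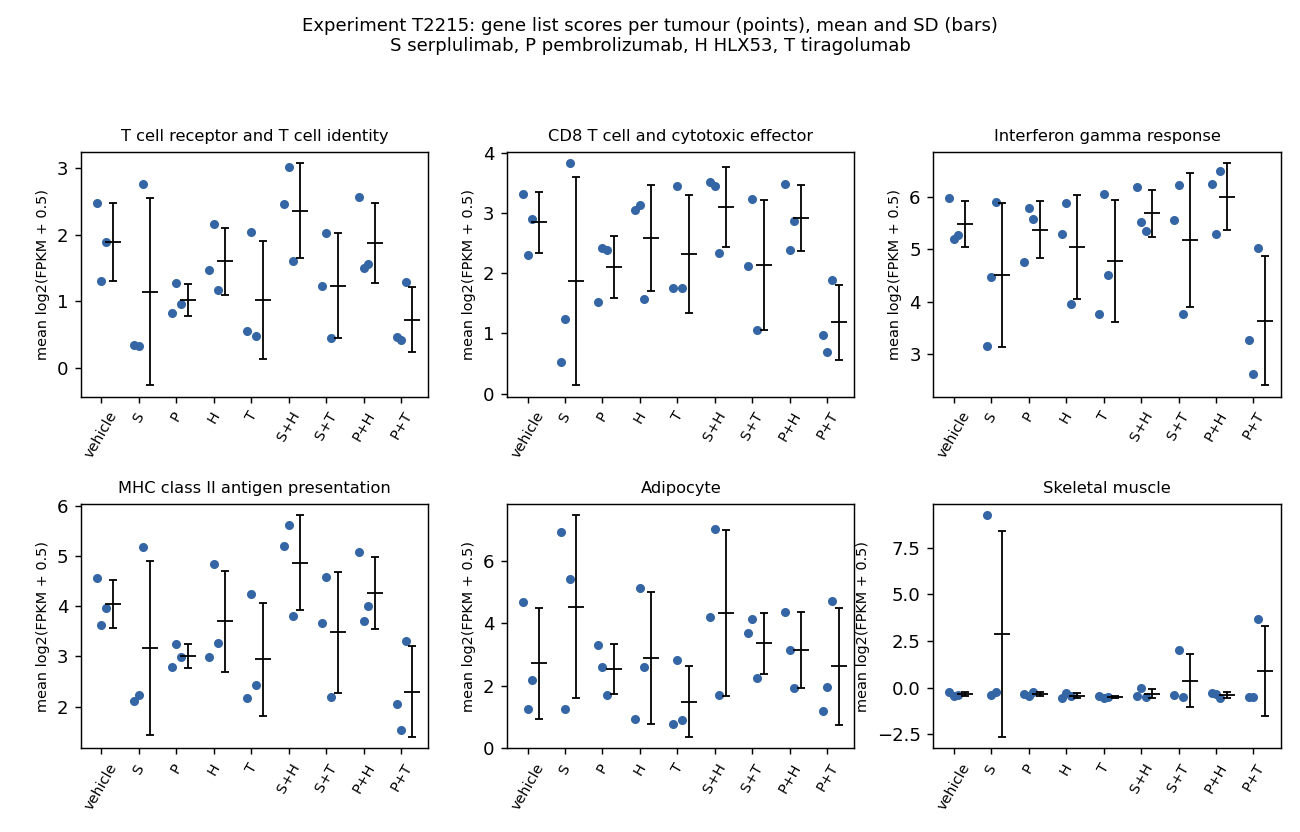
Mean log2(FPKM + 0.5) of 6 gene lists in the 27 tumours of T2215, with a point per tumour and bars for the mean and SD of each group. The interferon gamma score was 6.01 ± 0.637 with pembrolizumab and HLX53 and 3.65 ± 1.24 with pembrolizumab and tiragolumab, and 1 serplulimab tumour had a skeletal muscle score of 9.24.

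Each T2215 group was also set against vehicle, 3 tumours against 3. Pembrolizumab with HLX53 raised 1 gene model, Gm43802 (ENSMUSG00000105338; chromosome 3, 142547882 to 142548518), by 4.17 ± 0.63 (adjusted p = 0.0263 by limma; 959 genes at an unadjusted p under 0.05). It stood at 9.43 ± 4.75 FPKM (SD) against 0.00137 with vehicle and 1.53 ± 2.07 with HLX53 alone. Gm43802 is a processed pseudogene that overlaps the interferon-induced gene Gbp7 on the same strand, so its reads could belong to either, and it was named after its value was seen. The count was 0 without any 1 vehicle library or replicate 1 of the pair and 2 without replicate 2 of the pair. With pembrolizumab and tiragolumab 2610021A01Rik was higher by 1.61 ± 0.22 (adjusted p = 0.0032) and Gm43199 by 2.16 ± 0.23 (adjusted p = 7.78e-05). The same treatment in T2106 had 2610021A01Rik at 6.91 to 7.91 FPKM, against 7.83 to 8 with vehicle, and Gm43199 at no more than 1.62e-05, so these differences are not assigned to the antibodies. In T2215 1 gene passed without replicate 3 of this pair, and 655 had an unadjusted p under 0.05 with all tumours. In that group interferon gamma response had a median of −1.88 (17 of 24 lower adjusted over the list alone), MHC class I −1.16 (10 lower adjusted over the list alone), CD8 and cytotoxic −1.84 and natural killer −1.30, none past the test (adjusted p = 0.252 each; 4 lists unadjusted by fry, 0 called by camera with 4 unadjusted). Cd8a stood at −2.34 ± 0.95 (adjusted p = 1), Cxcl9 at −2.64 ± 1.02 and Gzmb at −2.08.

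The other T2215 groups had 0 genes past limma's test against vehicle. Serplulimab with HLX53 had cell cycle genes at a median of −0.74 (22 of 23 lower adjusted over the list alone, adjusted p = 0.21) and neutrophil genes at 1.68 (2 adjusted over the list alone, 0.215), with Mki67 at −0.75 ± 0.24 (adjusted p = 0.239), Havcr2 at 1.36 (0.24), Tigit at −0.72 (0.346) and Cd8a at 0.05 (0.981). Serplulimab alone had Cd8a at −1.44 ± 0.95 (adjusted p = 0.504), Cxcl9 at −2.00 (0.419) and Mki67 at −0.68 (0.387). Cd8a stood at −1.67 with pembrolizumab, −0.83 with HLX53, −1.61 with tiragolumab and −1.64 with serplulimab and tiragolumab (adjusted p = 1 each), and at −0.52 with pembrolizumab and HLX53 (0.906). Genes at an unadjusted p under 0.05 numbered 2729 with serplulimab and HLX53, 1842 with serplulimab, 201 with HLX53, 150 with pembrolizumab, 150 with serplulimab and tiragolumab and 140 with tiragolumab. Without its replicate 2 serplulimab called 1395 genes, not assigned to the antibody, since replicate 1 had a muscle score of 9.24 (vehicle mean −0.343). Without its replicate 3 serplulimab with HLX53 called 12. By fry 0 lists passed in these groups, where serplulimab with HLX53 had 2 at an unadjusted p under 0.05 and the others 0. Camera called 0, with 3 unadjusted for HLX53, 2 for tiragolumab, 1 each for pembrolizumab and serplulimab with tiragolumab, and 0 for the others.

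Serplulimab with HLX53 against pembrolizumab with tiragolumab in T2215 had the antigen presentation and interferon genes at higher values. MHC class II had a median of 2.79 (10 higher adjusted over the list alone), interferon gamma response 2.14 (20), CD8 and cytotoxic genes 1.96 (15), T cell genes 1.44 (21) and MHC class I 1.12 (12, each adjusted over the list alone), and all missed the test (adjusted p = 0.0659, and 0.346 with an estimated correlation). Cd3e stood at 2.00 ± 0.75, Cd8a at 2.39 ± 0.95, Gzmb at 2.62 ± 1.07, Cxcl9 at 2.84 ± 1.02, Cd274 at 2.38 ± 0.86, Havcr2 at 1.75 ± 0.51 and Tigit at −1.20 ± 0.43, with adjusted p from 0.222 to 0.265 over the panel (SE, n = 3 in each group). The genes past limma's test were 2610021A01Rik (−1.82 ± 0.22, adjusted p = 0.000446) and Gm43199 (−2.16 ± 0.23, adjusted p = 7.78e-05), 2 in all, with 3180 at an unadjusted p under 0.05. By fry 0 lists passed with 11 unadjusted, and camera called 0, with 0 unadjusted. Without replicate 3 of serplulimab and HLX53 there were 14 genes and 11 lists, without replicate 3 of pembrolizumab and tiragolumab 11 lists, and without the muscle-rich tumours, of which that same replicate 3 was the 1 in this comparison and the highest of its group in both scores below, which widens the difference by itself, 10 lists, all up, with MHC class II at 3.32 and interferon gamma response at 2.76 (adjusted p = 0.0289 each).

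**Figure D4:**
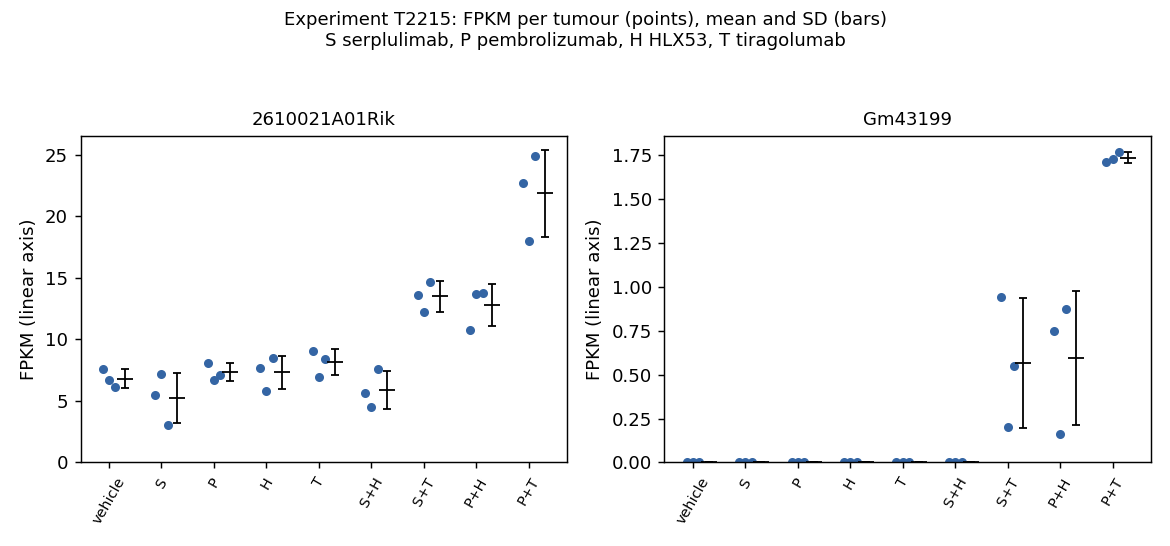
FPKM of 2610021A01Rik and Gm43199 in each tumour of the 9 groups of T2215, on a linear axis. In the 9 tumours given serplulimab with tiragolumab, pembrolizumab with HLX53 or pembrolizumab with tiragolumab, 2610021A01Rik was at 10.8 to 24.9 FPKM, against 3.05 to 9.08 in the other 18.

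The experiments shared 4 treatments, each with its own vehicle group, and the log2 fold changes of 14646 genes were compared between them. Across genes, which are not independent replicates, the correlation was 0.881 for serplulimab with HLX53 (jackknife SE 0.258, range 0.603 to 0.916 when 1 library was left out). With this treatment the adipocyte score was higher (effects of 3.89 in T2106 and 1.60 in T2215) and the cell cycle score lower (−0.96 and −0.75). The T2215 tumours given it had adipocyte scores of 4.21, 7.02 and 1.71. The correlation cannot tell the treatment from tissue content that differed the same way in both experiments. It was 0.346 for serplulimab (SE 0.278, muscle-rich T2215 replicate 1 included), 0.242 for HLX53 (SE 0.277) and 0.09 for pembrolizumab with tiragolumab (SE 0.164). Unmatched treatments gave −0.13 to 0.683, the highest between serplulimab in T2106 and serplulimab with HLX53 in T2215. The list effects did not pass a permutation test of their difference for any of the 26 lists and 4 treatments (smallest adjusted p = 0.52). Relabelling within each experiment assumes no effect in either, so it cannot test whether effects are equal. It also had little room to pass, since 400 relabellings give no p under 0.005 and at least 11 tests at that value would be needed. The 0.52 belonged to 2 lists for pembrolizumab with tiragolumab (exact permutation p = 0.01 each). Interferon gamma response was at 0.60 in T2106 and −1.84 in T2215, and natural killer genes at 0.42 and −1.19. Interferon gamma response also had opposite signs for serplulimab, at 0.56 and −0.97 with the muscle-rich tumour included (exact permutation p = 0.1). For HLX53 it was at 0.89 and −0.44 (0.105).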

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

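The fits without the muscle-rich tumours and with the adipocyte score as a covariate were chosen after the results were seen. Leaving out a library kept the side of the threshold in 4832 refits of a named gene, and moved 465 below the threshold and 37 above it. A change of sign was counted as a reversal only where the gene passed in either fit, and 0 were found. Genes that passed in neither fit were counted as the same whatever their sign. Under the other alternatives 4206 values of named genes kept the side of the threshold, 346 fell below it and 27 passed it. By the same rule 38 reversed, all of them with the adipocyte covariate. For each change the cause was not tested, except that fits with fewer libraries or an added covariate have fewer residual degrees of freedom by construction. The depth behind the values is unknown, so its limits were not estimated.

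A pseudocount of 0.1 gave 0 genes for HLX53 against vehicle in T2106, 5 for serplulimab and HLX53 against serplulimab, 1 for the higher against the lower dose, and in T2215 1 for PD-1 antibody against none and 0 for pembrolizumab and HLX53 against vehicle. A pseudocount of 1 gave 37 genes for the higher against the lower dose. Without the filter the T2106 counts were 4 for serplulimab, 5 for HLX53, 35 for the lower dose, 3471 for the higher dose (2266 higher, 1205 lower, 2666 shared with the filtered fit) and 3 for pembrolizumab and tiragolumab against vehicle. They were 410 against serplulimab, 157 against the lower dose and 3953 against pembrolizumab and tiragolumab for the higher dose. In T2215 no filter gave 4 for PD-1 antibody, 6 for TIGIT antibody, 2 for serplulimab against pembrolizumab, 4 for HLX53 against tiragolumab and 4 for the interaction. Against vehicle it gave 1 for pembrolizumab, 1 for HLX53, 2 for serplulimab and HLX53, 0 for pembrolizumab and HLX53 and 5 for pembrolizumab and tiragolumab, and 6 between the pairs.

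Median centring gave 1 list for serplulimab in T2106, 81 genes (62 higher, 19 lower, 69 shared) and 6 lists (5 up, 1 down) for the lower dose, and 1 gene for PD-1 antibody in T2215. Camera with an estimated correlation called 1 list for serplulimab, 1 for the lower dose, 0 for the higher dose and 1 for pembrolizumab and tiragolumab, each against vehicle in T2106. For the higher dose it called 0 against serplulimab, 1 against the lower dose and 0 against pembrolizumab and tiragolumab. With only the groups compared in the fit, T2106 gave 0 genes and 2 lists for HLX53, 0 genes and 0 lists for the lower dose, 4 lists for the higher dose against serplulimab, and 0 genes and 0 lists for the higher against the lower dose. T2215 gave 1 gene for serplulimab and HLX53, 1 for serplulimab and tiragolumab, 0 for pembrolizumab and HLX53 and 1 between the pairs.

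With the replicate number as a block T2106 gave 0 genes for HLX53, 39 for the lower dose, 114 for the higher dose against serplulimab and 10 against the lower dose, and T2215 gave 0 for TIGIT antibody. The numbers did not pair the tumours. Libraries with the same number in different groups deviated from their group means with a median correlation of −0.026 in T2106 (11 of 45 pairs above 0.1) and −0.039 in T2215 (42 of 108). A library correlated best with its own number in 31 of 90 searches of another group in T2106 and in 68 of 216 in T2215, so not every sample did, and the block is not a measure of a weaker effect.

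Without the muscle-rich tumours (in T2106 replicate 2 of the lower dose, in each comparison) T2106 gave 1 gene for serplulimab, 17 genes and 1 list for the lower dose, 5778 genes and 11 lists for the higher dose against serplulimab, and 5867 genes and 14 lists against the lower dose. T2215 gave 1 gene for PD-1 antibody, 1 for TIGIT antibody, 1 for pembrolizumab and tiragolumab, 15 lists for HLX53 against tiragolumab and 10 lists between the pairs. With the adipocyte score as a covariate T2106 gave 0 genes for HLX53, 79 (39 higher, 40 lower, 56 shared) for the lower dose, and 3 genes (2 higher, 1 lower, 2 shared) and 2 lists for the higher dose against vehicle. The higher dose gave 1 gene and 1 list against serplulimab, 1 gene against the lower dose, and 0 genes and 0 lists against pembrolizumab and tiragolumab.

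The reversed values of the higher dose against vehicle with the adipocyte covariate were Lrrc32 −0.158, Klf2 −0.05, Cd74 −0.12, H2-Aa −0.025, H2-DMb1 −0.044, Pecam1 −0.037 and Cd4 −0.03, none past the threshold. Against pembrolizumab and tiragolumab they were Cd4 −0.022, Entpd1 −0.105, Cd226 −0.379, Btla −0.065, Lrrc32 −0.6, Foxp3 −0.136, Klf2 −0.005, S1pr1 −0.21, Ccr7 −0.232, Tcf7 −0.57, Cd22 −0.005, Ltf −0.207, Csf3r −0.351, Retnlg −0.119, Cd209a −0.17, Batf3 −0.084, Kit −0.171 and Hdc −0.331. They also held Cd74 −0.31, H2-Ab1 −0.506, H2-Eb1 −0.476, Tek −0.191, Eng −0.196, Retn −0.084, Cd3e −0.16 and Pdcd1 −0.394, and, from falls, Cdh26 0.113, Glod5 0.355, Slc14a1 0.494, Krt20 0.169 and Tigit 0.326.

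Leaving out 1 library of the groups compared in T2106 gave 1 to 3 lists for serplulimab, 0 to 1 genes and 1 to 2 lists for HLX53, 12 to 6082 genes and 1 to 20 lists for the lower dose, 505 to 7392 genes and 4 to 20 lists for the higher dose, and 0 to 2 lists for pembrolizumab and tiragolumab, each against vehicle. The higher dose gave 1 to 3479 genes and 2 to 11 lists against serplulimab, 1 to 5867 genes and 2 to 14 lists against the lower dose, and 1632 to 7301 genes and 9 to 16 lists against pembrolizumab and tiragolumab. In T2215 it gave 0 to 1 genes for PD-1 antibody, 0 to 6 for TIGIT antibody, 0 to 5 for serplulimab against pembrolizumab, and 0 to 22 genes and 0 to 11 lists for HLX53 against tiragolumab. Against vehicle it gave 0 to 1395 genes for serplulimab, 0 to 12 for serplulimab and HLX53, 0 to 2 for pembrolizumab and HLX53 and 1 to 2 for pembrolizumab and tiragolumab, and between the pairs 2 to 14 genes and 0 to 11 lists. A group left with 2 tumours was assumed to vary like the other groups.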

Other observations

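The tests of tissue markers without the filter, of fat, of scaling and of the treatment itself in T2106, the tests of muscle and without muscle-rich tumours in T2215, the search for genes that separated groups, and the exchange of whole groups were chosen after the results were seen.

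Stress and hypoxia genes had group values beside those of the comparisons. The immediate early and stress score was 3.96 ± 0.23 in the vehicle group of T2106 (SD, n = 3), 4.54 ± 0.01 with serplulimab, 4.45 ± 0.08 with HLX53, 4.69 ± 0.09 with serplulimab and HLX53 at 5 mg/kg, 4.37 ± 0.17 at 10 mg/kg, and 4.29 ± 0.06 with pembrolizumab and tiragolumab. The hypoxia and glycolysis score was 5.65 ± 0.92, 6.53 ± 0.17, 6.21 ± 0.02, 6.18 ± 0.25, 5.75 ± 0.10 and 6.42 ± 0.18 in the same order.

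Between the TIGIT antibodies in T2215, the difference of HLX53 minus tiragolumab in the interferon gamma score was 0.27 without a PD-1 antibody, 0.51 beside serplulimab and 2.36 beside pembrolizumab. For MHC class II it was 0.75, 1.39 and 1.97, for CD8 and cytotoxic genes 0.26, 0.97 and 1.73, and for T cell genes 0.58, 1.13 and 1.15, in the same order. Whether these differences vary with the PD-1 antibody was not tested.

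The gene models 2610021A01Rik and Gm43199 stood apart in T2215, found after their values were seen. In all 9 tumours given serplulimab with tiragolumab, pembrolizumab with HLX53 or pembrolizumab with tiragolumab, 2610021A01Rik was at 10.8 to 24.9 FPKM and Gm43199 at 0.162 to 1.77. In the other 18 tumours they were at 3.05 to 9.08 and at most 1.71e-05, tumours given serplulimab with HLX53 among them. In the T2106 tumours given pembrolizumab with tiragolumab they were at 6.91 to 7.91 and at most 1.62e-05. Of the 84 choices of 3 groups 82 had no gene of 14914 above all other tumours, and the highest of the other choices had 1. Whether these 9 tumours shared a batch, a mouse substrain or a way of handling is not given in the sources used here and was not tested, so the calls on these 2 genes are not assigned to an antibody.

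A hypothesis for the broad rise with serplulimab and HLX53 at 10 mg/kg in T2106 is that these samples held tissue around the tumour. The median log2 fold change of all genes (−0.039) cannot judge scaling, since FPKM are scaled per library. Tissue markers were read with no filter on low values, since the filter keeps a low gene only where it rose. They could have stayed flat and did not. The median was 1.09 over all 12 mammary genes. Prlr stood at 3.15, Tnfsf11 at 2.99 and Cited1 at 2.49. The most abundant, Csn3, stood at 0.39, Foxa1 at −0.61 and the milk genes Csn2 at 0.06 and Wap at 0.05. Over all 7 lymph node genes the median was 1.16 (Cxcl13 at 5.15, Ccl19 at 2.04, Ccl21a at 0.56, Chst4 at 0.31). Tumours of other groups reached marker scores of 0.75 and 1.21, above the lowest of these samples (0.715 and 0.122). Since 17 of 26 lists rose by fry in this comparison, these markers cannot tell sampled tissue from the broad rise itself. With the adipocyte score as a covariate 2 of the 6633 genes passed. The median absolute change of the 6633 went from 0.979 (SE 0.283) to 0.266 (SE 0.318), so the calls ended mainly because the estimates shrank. The score could also remove part of a treatment effect. The treatment itself cannot be told apart from the sampled tissue. In T2215 0 lists passed, and all 26 effects had the same sign (neutrophil 1.78 against 3.12 in T2106, adipocyte 1.60 against 3.89). The lists are not independent, so these signs are not separate evidence, and the test of the effects' difference cannot decide.

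For the lower immune values with tiragolumab than with HLX53 in T2215 the candidates were muscle and fat in the samples. Leaving out the muscle-rich tumours (interferon gamma median 1.48, 15 lists) cannot tell muscle apart. The 2 in the comparison were tiragolumab tumours with the highest interferon gamma score of their group, which widens the difference by itself. With all 27 tumours and the muscle score as a covariate the median was 1.03 (adjusted p = 0.0869), against 1.09 (0.0858) without it. By fry 0 lists passed either way. With the adipocyte score as a covariate in the 24 other tumours, and so with the same tumours left out, that median was 1.21 (adjusted p = 0.0661), while MHC class II at 1.16 (adjusted p = 0.0108), T cell genes at 0.68 (0.0368) and the regulatory and the naive and memory lists passed, 4 of 26 in all. Fat cannot be told apart from the antibody for the interferon genes, since the covariate left a value of nearly that size on the other side of the threshold. The difference between the antibodies stays open.

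A hypothesis for mouse Tigit is that most of its transcript came from cells other than T cells. Its correlation in T2215 was −0.608 with the T cell score, where transcript from T cells would have given a positive value, and 0.721 with the cell cycle score, which a source in dividing tumour cells would give and which could have come out at or below 0. With values within groups both kept their sign (−0.454 and 0.689), which was given no test. Without the 2 farthest tumours r with the cell cycle score was 0.472. A lower share of tumour cells in T cell-rich samples would give the same signs for any gene of the tumour cells, so which cells hold the transcript stays open, as does how the knock-in alleles change the reads assigned to the mouse gene.

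Other splits of the same tumours were refitted. With 3 tumours against 3 there are 10 splits, too few for a share under 0.05, and the real value and the highest of the other splits are given in that order. In T2106 the genes were 0 and 1 for serplulimab, 1 and 0 for HLX53, 154 and 14 for the lower dose, 6633 and 0 for the higher dose, and 0 and 0 for pembrolizumab and tiragolumab, each against vehicle. For the higher dose they were 240 and 0 against serplulimab, 21 and 7955 against the lower dose, and 6414 and 1 against pembrolizumab and tiragolumab. The lists were 2 and 0, 1 and 0, 3 and 9, 18 and 0, 0 and 0, 2 and 0, 3 and 15, and 16 and 0 in the same order. The 7955 genes of a split of the doses, and the 9 lists of a split of the lower dose and vehicle, point to a structure of the samples that the groups do not follow. Between 1 and 10 of the 10 splits were as large as the real one, with 2 for the lists of the lower dose and for both counts of the doses.

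In T2215 the same order gave genes of 0 and 5 for serplulimab, 0 and 1 for serplulimab with HLX53, 1 and 0 for pembrolizumab with HLX53, 2 and 0 for pembrolizumab with tiragolumab, 2 and 0 between the pairs, and 0 and 0 for the other groups against vehicle. The lists were 0 and 4 for serplulimab, 0 and 1 for serplulimab with HLX53, 0 and 1 between the pairs, and 0 and 0 for the rest. For the crossed comparisons 100 splits were drawn. TIGIT antibody against none gave 2 genes and the highest other split of single tumours 1, 1 of 100, but 3 whole groups carried both genes. When whole groups were exchanged, 16 of 84 choices gave as many genes and the highest other gave 3, so chance is not excluded. HLX53 against tiragolumab without the muscle-rich tumours gave 15 lists and the highest other split 10, 1 of 100, in a fit chosen after the results were seen that took 2 tumours from the tiragolumab arm and 0 from the HLX53 arm. It therefore does not exclude chance for the difference between the antibodies, where all tumours gave 0 lists. For the counts of 0 the splits decide nothing, since any of the 100 equals or exceeds 0 by construction. The highest others were 2729 genes and 13 lists for PD-1 antibody, 14 lists for TIGIT antibody, 2733 genes and 4 lists for serplulimab against pembrolizumab, 1 gene and 1 list for HLX53 against tiragolumab, and 1 gene and 13 lists for the interaction. The splits with 2729 and 2733 genes point to a structure of the tumours other than the groups.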
